A study of Mus musculus with 4 samples.

How the data were processed

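RNA sequencing of total RNA was analysed from 4 libraries of mouse CB6F1 cells labelled MSCs, which the labels' protocols describe as isolated by digesting unfractionated bone marrow and then cultured. Per the labels' protocols, 2 libraries came from cells treated with R at 0.5 µM and 2 from cells treated with DMSO as vehicle. The labels do not say what R is, and write the dose unit as "um", which is read here as micromolar. Groups and replicate numbers were taken from the treatment labels and sample titles.

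The deposited table holds 1 FPKM value per gene and library for 54532 Ensembl genes, per the file headers, a read abundance scaled to gene length and library size. Its 10 empty unnamed columns were not used. The genome builds GRCm38 and mm10 are named per the submitters' processing notes, as is edgeR 3.18.1, which the submitters used in a role they do not state. The aligner, the counting tool, the gene annotation and the filters are not given in the sources used here. FPKM multiplied by the union exon length in GENCODE M21 gave whole reads, within a tolerance of 0.02, for 96.3 to 96.4% of values above 0. The library sizes by which the values had been divided, relative to the recovered reads, were 1.004, 1.029, 0.981 and 0.987 for R replicates 1 and 2 and vehicle replicates 1 and 2, on a scale with a geometric mean of 1, and the TMM factors of the recovered reads were 1.004, 1.029, 0.982 and 0.985. The values therefore include a scaling beyond the number of reads, and FPKM sums differed between libraries, from 287360 to 345709.

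Of the gene identifiers, 54495 matched GENCODE M21 (GRCm38), which gave symbols, coordinates, biotypes and lengths, and 37 did not match and have no symbol. Coordinates are 1-based. Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of genes with low values. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 12176 in all. Recovered reads per library were 16570419 to 18140519, so a gene of 2 kb at 1 FPKM corresponded to about 36 reads.

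R was compared with vehicle in limma 3.58.1 under R 4.3.3, with a linear model without further terms, a variance trend with mean expression (eBayes, trend) and Benjamini-Hochberg adjustment over the genes tested, at an adjusted p under 0.05. The fit had 2 residual degrees of freedom and a prior of 3.83, and the median standard error of a log2 fold change was 0.148. Before the data were examined, 42 gene lists with 1119 genes were fixed, covering interferon, antigen presentation, inflammation, stromal and lineage programmes, metabolism and stress, and cell type markers. Of their genes 1111 matched the table. The 37 lists with at least 5 tested members were tested with limma's camera, with an inter-gene correlation preset at 0.01, and again with the correlation estimated per list and with fry. Camera asks whether the genes of a list move against the other tested genes. Fisher's exact test (two-sided) was used for the overlap of the interferon list with the genes that fell. Counts adjusted over a list alone used Benjamini-Hochberg adjustment over the tested members of that list. They are not adjusted over the 42 lists, some of which share genes.

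Named genes followed a rule fixed before the data were examined. It took the 8 largest positive and 8 largest negative log2 fold changes among called genes with a mean of at least 5 FPKM and groups that do not overlap, leaving out predicted genes and pseudogenes. It also took the 3 members with the smallest p, in the direction of the list, of up to 8 lists past the camera threshold, and the member with the smallest p of other lists discussed. The genes Cxcl12, Kitl, Lepr, Pdgfra, Runx2, Alpl, Pparg, Cdkn1a, Cdkn2a, Irf1, Socs3 and Ptprc were fixed checks, and 1 further fixed check is not reported here. Where a list had few called members these are named as well, which was decided after their values were seen.

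The scripts were tested on simulated libraries with 200 changed genes. In the simulation of R against vehicle, run on 12168 genes, 199 genes were called, 17 of them falsely. Of the genes with log2 fold changes of 1, 2, 3 and 4, 74, 94, 98 and 98% were recovered. With a gene length trend simulated in R replicate 2, 23 of 209 calls were false without a correction for it. With the correction 13 of 201 were false. In each of these runs the false share of calls was above the adjusted p threshold. In 20 simulated draws in which the interferon list was shifted by -1 on the log2 scale, camera with the preset correlation called it in 20 and camera with the estimated correlation in 0. None of 700 tests of unchanged lists in these draws was called with the preset correlation. Genes varied independently in the draws, so they cannot show how the preset performs where genes of a list vary together. In the data the estimated correlation ran from -0.083 for the osteoclast markers to 0.913 for the cytosolic ribosomal proteins.

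The alternatives tried before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 5 FPKM, the replicate number as a block, quantile normalization, rescaling to TPM, median centring, eBayes without a trend and with robust estimation, a log2 fold change of at least 1, and leaving out each library in turn. Added after seeing the data were the removal of each library's trend against log2 gene length (lowess, span 0.3), without and with the block, protein-coding genes only, voom on recovered reads, and lists without members of the interferon list. Figures were drawn with matplotlib 3.10.9.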

Results

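Gene expression was measured by RNA sequencing of total RNA from mouse bone marrow cells labelled MSCs and grown in culture. The mice were CB6F1, an F1 hybrid laboratory strain, and the sample titles carry the term aGVHD. The 2 R libraries came from cells given a compound that the labels call R, at 0.5 µM (written "um" in the labels), and the 2 vehicle libraries from cells given DMSO, the solvent, alone. The deposited table held FPKM values of 54532 genes, of which 24958 were above 0 in at least 1 library. The values corresponded to 18140519 and 16570419 recovered reads in R replicates 1 and 2 and to 16944196 and 17153248 in vehicle replicates 1 and 2. At this depth a gene of 2 kb at 1 FPKM corresponded to about 36 reads. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

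Macrophage transcripts were abundant in all 4 libraries. Lyz2, which encodes the lysozyme of myeloid cells, was at 7976 ± 1294 FPKM (SD, n = 2) in R and at 13550 ± 1435 FPKM (SD, n = 2) in vehicle. The median of 27 macrophage and monocyte markers was 182 and 143 FPKM in the R libraries and 247 and 253 FPKM in the vehicle libraries. The median of 27 mesenchymal stromal cell markers lay between 11.0 and 14.9 FPKM. Single members lay far above it, such as Cxcl12 at 488 ± 37.3 FPKM in R and 505 ± 17.4 FPKM in vehicle (SD, n = 2 each). Medians of lists with unlike genes do not give the shares of cell types. Markers of neutrophils and of T and NK cells had a median of 0 FPKM in each library, and those of erythroid cells a median of at most 0.042 FPKM. The first principal component held 59.2% of the variance of the tested genes and the second 30.0%. The R libraries differed from each other more than the vehicle libraries did, with an SD of log2 ratios of 0.351 against 0.248, and R replicate 2 had the smallest FPKM sum, 287360 against 333130 to 345709 in the other libraries.

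The comparison of R with vehicle asked which transcripts differ between cells given R and cells given the solvent. Interferon-stimulated genes were lower in R. Ifi27l2a, an interferon-induced gene, was at 7.69 ± 2.10 FPKM (SD, n = 2) in R and 288 ± 74.0 FPKM (SD, n = 2) in vehicle, a 37.4-fold lower mean. Ccl8, a chemokine that attracts monocytes, was at 0.473 ± 0.0957 FPKM (SD, n = 2) in R and 40.4 ± 5.62 FPKM (SD, n = 2) in vehicle. Among the 8 named genes with the largest log2 fold changes in each direction, those higher in R changed less. Adra1d, an alpha-1 adrenergic receptor, rose from 10.3 ± 0.878 to 26.0 ± 0.925 FPKM (SD, n = 2 each). Col2a1, the main collagen of cartilage, rose from 25.5 ± 1.59 to 54.6 ± 4.55 FPKM (SD, n = 2 each).

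Of 12176 genes tested with limma, 42 rose and 167 fell in R at a Benjamini-Hochberg adjusted p under 0.05. An unadjusted p under 0.05 was found for 1947 genes, against 609 that chance would give. Of the genes that fell, 138 were protein-coding and 129 had a log2 fold change of -1 or below. Of the genes that rose, 24 were protein-coding, 12 were predicted genes or pseudogenes, and 29 had a log2 fold change of 1 or above. The values of the 2 groups did not overlap in 47.9% of tested genes, where chance gives 33.3%. Rescaling each library to TPM gave 58 genes higher and 124 lower, with 68.1% of calls lower where the deposited scale gave 79.9%, and moved the median log2 fold change of all tested genes to 0.13. The counts also moved when 1 library was left out, to 331 higher and 698 lower without R replicate 1, 447 and 425 without R replicate 2, 100 and 183 without vehicle replicate 1, and 152 and 250 without vehicle replicate 2. A correction for a gene length trend, chosen after the data were seen, gave 222 genes higher and 349 lower. Without a filter on low values limma called 0 of 24958 genes after Benjamini-Hochberg adjustment, with 2767 at an unadjusted p under 0.05.

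The interferon-stimulated genes formed the list with the smallest p. All 54 tested members had log2 fold changes below 0, with a median of -1.44 on the log2(FPKM + 1) scale, which understates the change of genes with low values. Of these, 40 fell when adjusted over all genes and 53 fell when adjusted over the list alone. Counts over a list alone, here and below, are not adjusted over the number of lists. The 40 genes made up 24.0% of all genes that fell (Fisher's exact test, two-sided, odds ratio 267, p = 5.68e-65). This test treats genes as independent, and its p does not measure the spread between samples. In limma's camera test with a preset correlation the list was lower in R at a Benjamini-Hochberg adjusted p = 2.35e-57, and this call was lost with an estimated correlation (adjusted p = 0.0911). The estimate was -0.006, below the preset 0.01, so correlation within the list cannot be why the call was lost. Camera with an estimated correlation also called the list in 0 of 20 simulated draws in which it was shifted. The macrophage marker list was lower as well, with a median log2 fold change of -0.59. Rtp4, an interferon-induced member of the receptor transporter protein family, fell by 3.68 on the log2 scale (SE 0.168; limma, Benjamini-Hochberg adjusted p = 0.0019). Oas2 and Oasl2, members of the family of oligoadenylate synthetases that sense double-stranded RNA, fell from 14.9 ± 0.195 to 0.325 ± 0.0319 FPKM and from 14.97 ± 0.0934 to 0.678 ± 0.108 FPKM (SD, n = 2 each). Their log2 fold changes were -3.58 and -3.25, with limma's Benjamini-Hochberg adjusted p = 0.000906 and adjusted p = 0.0012. Ifit1 and Ifit3, interferon-induced proteins that restrict viral RNA, fell by 3.01 and by 2.90 on the log2 scale. Ifit3 has a close copy, Ifit3b, so reads between them could be split. Irf7, a transcription factor that amplifies type I interferon production, fell from 9.88 ± 0.993 to 0.583 ± 0.224 FPKM (SD, n = 2 each). Irf1, an interferon-responsive transcription factor, did not pass the test, at 9.53 ± 0.169 FPKM in R and 12.1 ± 0.806 FPKM in vehicle (SD, n = 2 each).

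**Figure D1:**
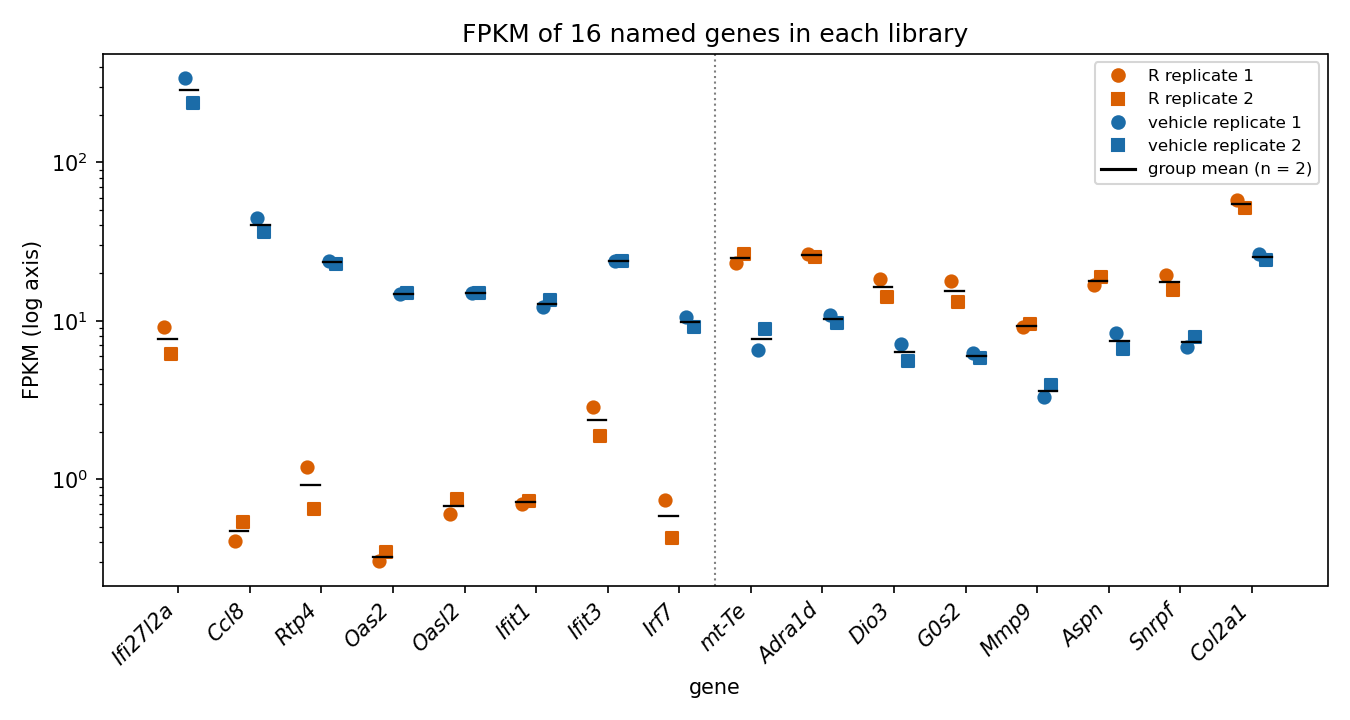
FPKM (log axis) of the 16 genes with the largest fold changes in either direction among genes past the threshold with a mean of at least 5 FPKM, in each of the 4 libraries, with black bars for group means (n = 2). Ifi27l2a lies at 9.18 and 6.21 FPKM in the R libraries and at 340 and 236 FPKM in the vehicle libraries, and Col2a1 at 57.8 and 51.3 against 26.6 and 24.3 FPKM.

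In the GRCm38 annotation of GENCODE M21, Ifi27l2a (ENSMUSG00000079017) spans positions 103442167 to 103443680 of chromosome 12 and Ccl8 (ENSMUSG00000009185) positions 82115185 to 82116799 of chromosome 11. Oas2 (ENSMUSG00000032690) lies at 120730333 to 120749853 and Oasl2 (ENSMUSG00000029561) at 114896936 to 114912234 of chromosome 5. Ifit1 (ENSMUSG00000034459) and Ifit3 (ENSMUSG00000074896) lie on chromosome 19, at 34640871 to 34650009 and 34583531 to 34588731. Col2a1 (ENSMUSG00000022483) lies at 97975602 to 98004695 of chromosome 15 and Adra1d (ENSMUSG00000027335) at 131545850 to 131562283 of chromosome 2. The values cover whole genes, summed over annotated exons.

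The list of MHC and antigen presentation genes was lower in R in camera with a preset correlation. All 29 tested members had log2 fold changes below 0, with a median of -0.64. Of these, 5 fell when adjusted over all genes and 18 when adjusted over the list alone. The camera test gave a Benjamini-Hochberg adjusted p = 1.31e-13, which was lost with an estimated correlation (adjusted p = 0.469) and in fry (adjusted p = 0.0961). Of 5 tested class II genes 0 were called. The class I genes H2-T23, H2-Q6 and H2-Q4 fell by 1.15, by 1.33 and by 1.23 on the log2 scale, with limma's Benjamini-Hochberg adjusted p = 0.0132, adjusted p = 0.0153 and adjusted p = 0.0231. H2-Q6 and H2-Q4 belong to a family of near-identical copies, so their values are uncertain. B2m, the light chain of class I molecules, was at 1158 ± 95.7 FPKM in R and 2917 ± 400 FPKM in vehicle (SD, n = 2 each) and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.056). It passed in 9 of 16 alternatives without a replicate block, among them TPM, voom and the length correction, with limma's Benjamini-Hochberg values from adjusted p = 0.00508 to adjusted p = 0.687. The macrophage marker list, with a median log2 fold change of -0.59, was lower in the same libraries.

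Of 25 tested macrophage and monocyte markers, 23 had log2 fold changes below 0. The median was -0.59 on the deposited scale, -0.35 after quantile normalization and -0.46 on the TPM scale. In this list 5 genes fell when adjusted over all genes and 13 when adjusted over the list alone. The camera test gave a Benjamini-Hochberg adjusted p = 2.29e-08, which was lost with an estimated correlation (adjusted p = 0.338). Fcgr1, the high-affinity receptor for IgG, fell from 40.0 ± 0.867 to 10.1 ± 2.08 FPKM (SD, n = 2 each; limma, Benjamini-Hochberg adjusted p = 0.00728). Ctss, a lysosomal protease of antigen-presenting cells, fell from 781 ± 43.5 to 317 ± 37.9 FPKM (SD, n = 2 each). Without vehicle replicate 1 or 2 its call was lost, with limma's Benjamini-Hochberg adjusted p = 0.209 and adjusted p = 0.103. Ly86, a partner of a toll-like receptor homologue, fell by 1.11 on the log2 scale. Other members changed less. Among them Csf1r, Adgre1 and Mrc1, chosen after their values were seen, had log2 fold changes of -0.26, -0.13 and -0.19 and were not called. Ptprc, the leukocyte common antigen, did not pass the test, at 8.57 ± 1.26 FPKM in R and 12.8 ± 1.495 FPKM in vehicle (SD, n = 2 each).

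Further lists of inflammatory genes were lower in R in the camera test, in the same libraries as the macrophage markers. Of the tested members, 22 of 27 secretory factors and 15 of 28 NF-kB genes are also in other lists. The same holds for 7 of 23 STAT genes and 3 of 11 complement genes, so these lists are not independent results. Saa3 is in both the complement and the STAT list. Of 11 tested complement and acute phase genes, 3 fell when adjusted over all genes and 6 when adjusted over the list alone. These were C4b and Saa3, a complement component and an acute phase protein, and Cp, the copper carrier ceruloplasmin, with log2 fold changes of -1.56, -1.52 and -0.90. C4b has a close copy, so its value is uncertain. Of 23 tested genes of STAT feedback and cytokine-induced STAT targets, 5 fell when adjusted over all genes, and 11 fell and 1 rose when adjusted over the list alone. Il4ra, the receptor subunit for interleukin 4, fell from 69.0 ± 1.09 to 34.5 ± 1.43 FPKM, and Bcl3, a nuclear NF-kB cofactor, fell from 10.7 ± 0.0800 to 4.98 ± 0.414 FPKM (SD, n = 2 each). Socs3, a feedback inhibitor of cytokine signalling, did not pass the test, at 40.1 ± 0.510 FPKM in R and 45.8 ± 1.80 FPKM in vehicle (SD, n = 2 each). Of 28 tested genes of the NF-kB list, 3 fell when adjusted over all genes, and 13 fell and 2 rose when adjusted over the list alone. These 3 were Ccl8 and Cxcl5, which encode chemokines, and Il1b, which encodes interleukin 1 beta, with log2 fold changes of -4.81, -1.59 and -0.94. Of 27 tested secretory factors of senescent cells, 5 fell when adjusted over all genes, and 9 fell and 1 rose when adjusted over the list alone. These 5 were Ccl8, Cxcl5, Il1b and the matrix proteases Mmp3 and Mmp13. The median log2 fold changes of the complement, STAT, NF-kB and secretory factor lists were -0.53, -0.40, -0.32 and -0.37, with Benjamini-Hochberg adjusted p = 6.4e-06, adjusted p = 4.43e-05, adjusted p = 0.00026 and adjusted p = 0.000721 in limma's camera. Each of these 4 calls was lost with an estimated correlation (adjusted p = 0.282 for each).

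The call of Il4ra was lost without vehicle replicate 1 or 2, at adjusted p = 0.11 and adjusted p = 0.0632 in limma with Benjamini-Hochberg adjustment. The call of Il1b was lost without vehicle replicate 1 (adjusted p = 0.0707) and on the TPM scale (adjusted p = 0.0919), and that of Cp on the TPM scale (adjusted p = 0.0976), in limma with Benjamini-Hochberg adjustment.

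**Figure D2:**
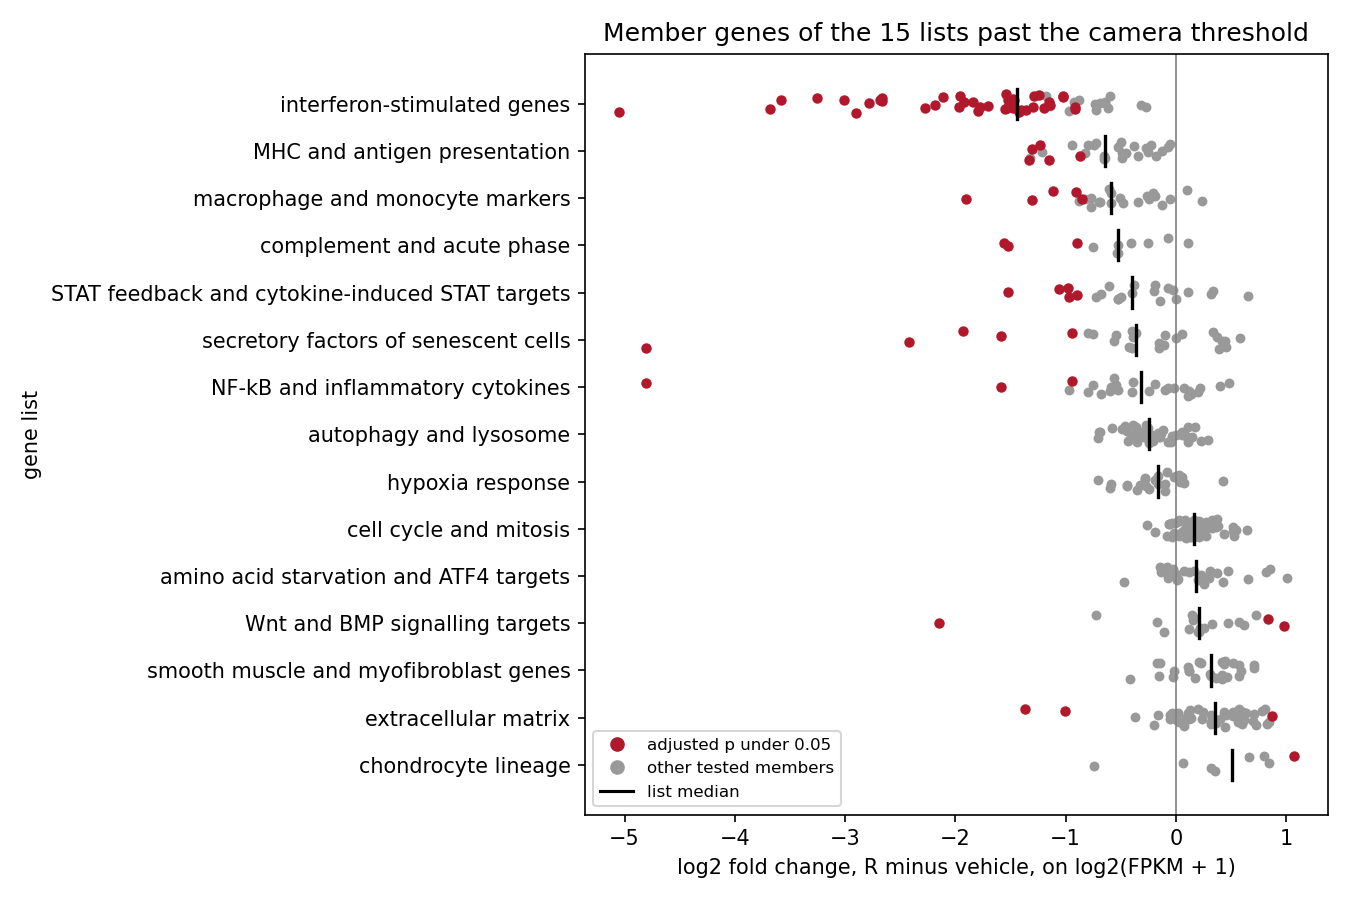
Log2 fold changes (R minus vehicle, on log2(FPKM + 1)) of each tested member of the 15 gene lists past the camera threshold; red points passed an adjusted p under 0.05, grey points did not, and black bars are list medians. The 54 interferon-stimulated genes all lie below 0 with a median of -1.44, and the extracellular matrix genes have a median of 0.36 with Lum at -1.37 and Dcn at -1.01.

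Extracellular matrix genes were higher in R as a list, in the libraries where macrophage markers were lower. Of 52 tested members, 43 had log2 fold changes above 0 and the median was 0.36. In this list 1 gene rose and 2 fell when adjusted over all genes, and 17 rose and 2 fell when adjusted over the list alone. The camera test gave a Benjamini-Hochberg adjusted p = 7.63e-08, which was lost with an estimated correlation (adjusted p = 0.318). The gene that rose was Col5a3, a fibrillar collagen chain, from 2.82 ± 0.186 to 5.996 ± 0.409 FPKM (SD, n = 2 each). Its call was lost without vehicle replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0783). The genes that fell were Lum and Dcn, small proteoglycans that bind collagen, with log2 fold changes of -1.37 and -1.01. Fbln5 and Col4a1, which encode an elastic fibre protein and a basement membrane collagen, had log2 fold changes of 0.70 and 0.82 and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.0555 and adjusted p = 0.0569). Each passed in 6 of the same 16 alternatives, voom and the length correction among them. Voom on recovered reads called 7 matrix genes higher and 2 lower of 49 tested.

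Of 8 tested genes of the chondrocyte lineage, 1 rose when adjusted over all genes, and 5 rose and 1 fell when adjusted over the list alone. The gene that rose was Col2a1, and without vehicle replicate 2 its call was lost (limma, Benjamini-Hochberg adjusted p = 0.056). Of 19 tested Wnt and BMP signalling targets, 2 rose and 1 fell when adjusted over all genes, and 6 rose and 2 fell when adjusted over the list alone. Nkd1 and Smad6, feedback inhibitors of Wnt and BMP signalling, rose by 0.98 and 0.83 on the log2 scale, and Sfrp4, a secreted Wnt antagonist, fell from 64.3 ± 0.0911 to 13.7 ± 0.478 FPKM (SD, n = 2 each). The chondrocyte and Wnt and BMP lists had median log2 fold changes of 0.51 and 0.21 and Benjamini-Hochberg adjusted p = 0.00198 and adjusted p = 0.00691 in limma's camera. Both calls were lost with an estimated correlation (adjusted p = 0.313 and adjusted p = 0.469). Macrophage markers were lower in the same libraries, with a median log2 fold change of -0.59.

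In 5 further lists past the camera threshold, limma with Benjamini-Hochberg adjustment over all genes called 0 single members. The cell cycle list had a median log2 fold change of 0.16 over 57 genes, 9 of them at an unadjusted p under 0.05 and 0 called by voom on recovered reads. Its members with the smallest p were Mcm5, a DNA replication helicase subunit, at 14.8 ± 0.146 FPKM in R and 9.86 ± 0.677 FPKM in vehicle, the mitotic kinase Plk1 at 16.1 ± 0.802 and 10.9 ± 0.565 FPKM, and Cdc20 at 27.2 ± 2.71 and 17.1 ± 2.67 FPKM (SD, n = 2 each). The smooth muscle and myofibroblast list had a median of 0.32 over 27 genes, 8 at an unadjusted p under 0.05 and 2 called by voom. The list of ATF4 targets, genes of amino acid starvation, had a median of 0.18 over 28 genes, 7 at an unadjusted p under 0.05 and 1 called by voom. The autophagy and lysosome list had a median of -0.25 over 42 genes, 10 at an unadjusted p under 0.05 and 1 called by voom. The macrophage marker list, which shares Cd68 with it, was lower in the same libraries (median -0.59). The hypoxia list had a median of -0.17 over 25 genes, 7 at an unadjusted p under 0.05 and 1 called by voom. Adjusted over the list alone, 4 ATF4 targets rose, 1 autophagy and lysosome gene fell, and no member of the other 3 lists was called. In limma's camera they had Benjamini-Hochberg adjusted p = 4.46e-05, adjusted p = 0.000434, adjusted p = 0.00208, adjusted p = 0.000323 and adjusted p = 0.00572, in the order given, and all 5 calls were lost with an estimated correlation (adjusted p = 0.282, adjusted p = 0.282, adjusted p = 0.545, adjusted p = 0.495 and adjusted p = 0.313). The autophagy, hypoxia and Wnt and BMP calls were lost without vehicle replicate 1 (adjusted p = 0.0762 for each in camera) or 2, the hypoxia call also on the TPM scale (adjusted p = 0.0506) and among genes with a mean of at least 5 FPKM (adjusted p = 0.0902), the Wnt and BMP call also without R replicate 2 (adjusted p = 0.102), and that of the ATF4 targets without R replicate 1 (adjusted p = 0.142).

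Other named genes that rose were Dio3, which inactivates thyroid hormone, G0s2, an inhibitor of fat breakdown, Snrpf, a spliceosome protein, and Aspn, a proteoglycan of cartilage and periodontal tissue. Their log2 fold changes were 1.22, 1.21, 1.15 and 1.15. The mitochondrial tRNA gene mt-Te rose by 1.58 on the log2 scale but is 69 bases long and rests on 31, 33, 8 and 11 reads, and voom on recovered reads gave it an adjusted p = 0.135 (limma, Benjamini-Hochberg). Mmp9, a gelatinase held in the osteoclast, neutrophil and metalloproteinase lists, rose from 3.64 ± 0.428 to 9.31 ± 0.287 FPKM (SD, n = 2 each).

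The lists of mesenchymal stromal cell markers, osteoblast lineage, niche factors, adipocyte lineage, and senescence and p53 targets did not pass the camera test. Of 23 tested mesenchymal stromal cell markers, 0 rose and 3 fell when adjusted over all genes, and 7 rose and 3 fell when adjusted over the list alone. The 3 were Ly6a, also known as Sca-1, Lum and Dcn, and Ly6a fell from 84.4 ± 8.71 to 25.2 ± 4.53 FPKM (SD, n = 2 each). Pdgfra was at 12.8 ± 2.94 FPKM in R and 14.2 ± 0.514 FPKM in vehicle (SD, n = 2 each), and Lepr lay below the filter, at 0.316, 0.690, 0.466 and 0.522 FPKM in R replicates 1 and 2 and vehicle replicates 1 and 2. Of 25 tested genes of the osteoblast lineage, 1 rose (Omd, a bone proteoglycan) and 1 fell (Mmp13, a collagenase, from 184 ± 8.89 to 47.6 ± 6.59 FPKM, SD, n = 2 each), and 5 rose and 2 fell when adjusted over the list alone. Runx2 and Alpl, markers of early osteoblasts, had log2 fold changes of -0.02 and 0.09 and did not pass the test. Cxcl12 and Kitl, niche factors for blood stem cells, were at 488 ± 37.3 and 26.4 ± 6.61 FPKM in R and at 505 ± 17.4 and 20.02 ± 2.57 FPKM in vehicle (SD, n = 2 each) and did not pass the test. Of 25 tested niche factors, 0 were called over all genes or over the list alone by limma with Benjamini-Hochberg adjustment, 9 were at an unadjusted p under 0.05 and 0 were called by voom. As a list they passed as higher without R replicate 1. Bmp4 had the smallest p of them, with a log2 fold change of 0.49. Of 21 tested adipocyte genes, 0 were called over all genes and 4 rose when adjusted over the list alone, 5 were at an unadjusted p under 0.05 and 2 were called by voom. Pparg, the regulator of fat cell formation, and Plin4, a lipid droplet protein, had log2 fold changes of 0.24 and 0.81. Of 29 tested senescence and p53 targets, 0 were called over all genes or over the list alone by limma, 5 were at an unadjusted p under 0.05 and 0 were called by voom. Cdkn1a and Cdkn2a, inhibitors of the cell cycle, had log2 fold changes of -0.01 and 0.39 in this list, and Aen had the smallest p, with 0.57.

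The lists of cholesterol and fatty acid synthesis, glycolysis, heat shock, unfolded protein and NRF2 responses, immediate early genes, histones and reference genes did not pass the camera test either, nor did B cell, endothelial and osteoclast markers. Of these, the heat shock list passed as higher after quantile normalization, on the TPM scale and without R replicate 2, the fatty acid list as higher without R replicate 1, the histones as higher without vehicle replicate 1, and the cholesterol list as lower in fry. Immunomodulatory factors of stromal cells did not pass, and Il10, an anti-inflammatory cytokine and the member with the smallest p, was at 12.0 ± 1.41 FPKM in R and 22.6 ± 1.88 FPKM in vehicle (SD, n = 2 each) and was not called, but passed in 8 of the same 16 alternatives. The oxidative phosphorylation and cytosolic ribosomal protein lists did not pass, with median log2 fold changes of -0.01 and -0.14, and their signs depended on the R library. Without R replicate 1 the medians were -0.24 and -0.41, and without R replicate 2 they were 0.21 and 0.17. Camera called both lists lower in R without R replicate 1 and higher without R replicate 2. The mitochondrially encoded genes had a median of -0.13. The median, mean and test differed in sign for the osteoclast, oxidative phosphorylation, unfolded protein, mitochondrially encoded, glycolysis, metalloproteinase and immunomodulatory lists. Of the metalloproteinases, Mmp3, which degrades matrix proteins, fell from 9.02 ± 0.0648 to 0.873 ± 0.149 FPKM (SD, n = 2 each).

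With an estimated correlation camera called 0 of 37 lists, with 5 at an unadjusted p under 0.05, and fry, which tests whether a list's genes move on balance one way, called 9. The estimated correlation was below the preset 0.01 for the interferon, STAT, NF-kB, complement, secretory factor, chondrocyte, smooth muscle and hypoxia lists. Correlation within these lists therefore cannot be why their calls were lost. For the other called lists it ran from 0.012 (cell cycle) to 0.594 (MHC). In the simulation camera with the estimate called the shifted interferon list in 0 of 20 draws. A call lost there cannot show that a list is unchanged. Fry lost the calls of the MHC, macrophage, matrix, cell cycle, ATF4, autophagy, and Wnt and BMP lists. With 2 libraries per group, an exact two-sided permutation test of a single gene cannot give a p below 0.333, so the calls rest on the spread that limma pools over genes.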

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

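The length correction, the restriction to protein-coding genes, voom and the lists without interferon genes were chosen after seeing the data. No called gene changed sign in an alternative that tested it, which was fixed in advance for most of them. The values of the 2 groups did not overlap in any of the 209 called genes, so leaving out 1 library could not change a sign. Settings that keep the deposited values, such as the block, the filters and the changes to eBayes, could not do so either. Only the alternatives that rescale or correct the values could have changed one. Without a filter on low values, limma called 0 genes higher and 0 lower of 24958, with 2767 at an unadjusted p under 0.05. The length correction gave 222 genes higher in R and 349 lower, protein-coding genes alone gave 101 higher and 231 lower, and voom gave 83 higher and 235 lower. Of the named genes not called, 18 passed with the length correction, 12 among protein-coding genes and 11 with voom. Leaving out 1 library gave 100 to 447 genes higher and 183 to 698 lower, and a lone library in a group was then assumed to vary like the other group. Camera with an estimated correlation called 0 gene lists higher and 0 lower, and fry called 9 lists, 2 of them higher and the rest lower. In the simulation, where genes varied independently, the estimated correlation also missed the interferon list when it was shifted by a known amount. No other list was shifted there.

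The replicate numbers are shared by the groups, but the labels do not say that a number marks a shared animal or day, and there are only 2 pairs. Same-numbered libraries had a correlation of deviations of 0.353, and of 0.262 after the length correction. With the replicate block 891 genes were higher in R and 1009 lower, and 801 and 851 with the block and the length correction together. In the simulation 47 of 234 calls with the block were false. No effect of replicate number was simulated, so this cannot show how the block performs where libraries are paired. With the block 27 more named genes passed, and the Wnt and BMP list was lost (camera, Benjamini-Hochberg adjusted p = 0.0512).

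The direction of the camera test turned for the oxidative phosphorylation list without R replicate 1, where its median log2 fold change was -0.239 (0.212 without R replicate 2), and for the list of cytosolic ribosomal proteins without R replicate 2, at 0.167 (-0.407 without R replicate 1). Neither list passed in the main comparison with all 4 libraries. Both passed as lower without R replicate 1 and as higher without R replicate 2. The ribosomal list also passed as lower without vehicle replicate 2, on the TPM scale, without the trend, with the length correction, among protein-coding genes and with voom. On the TPM scale its median log2 fold change was -0.004, with 37 of 74 members below 0. The median of all tested genes was 0.13 on that scale, so this call rests on the comparison with the other genes. The cause of these changes was not tested. Depth limits genes near 1 FPKM, which rest on about 36 reads at 2 kb.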

Other observations

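Genes and families in this paragraph were chosen after their values were seen. No family was tested as a set. In the Slfn family 3 of 4 tested genes fell, and Slfn2 fell from 128 ± 0.794 to 26.0 ± 4.02 FPKM (SD, n = 2 each). In the Ifi200 family, whose products sense DNA, 7 of 8 tested genes fell, among them Ifi209 and Mndal with log2 fold changes of -2.30 and -1.99. In the Gbp family 2 of 6 tested genes fell, with all 6 below 0 and a median log2 fold change of -0.924. In the Parp family 2 of 12 tested genes fell, with 11 below 0 and a median of -0.297. Ly6c1 and Ly6e fell by 2.36 and by 2.08 on the log2 scale. The chemokine receptor gene Ccr1 had a log2 fold change of -1.88, and Cd5l, a protein secreted by macrophages, fell from 84.9 ± 1.85 to 16.02 ± 1.38 FPKM (SD, n = 2 each). In contrast, all 23 tested collagen genes had log2 fold changes above 0, with a median of 0.61 and 3 that rose. The medians of the Slfn, Ifi200 and collagen families kept their sign under each scaling tried.

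Components of interferon and cytokine signalling moved unequally in values chosen after they were seen. Stat2 fell from 12.7 ± 0.857 to 4.17 ± 0.294 FPKM, Irf9 from 11.2 ± 1.26 to 3.16 ± 0.207 FPKM and Jak3 from 10.5 ± 0.223 to 4.90 ± 0.652 FPKM (SD, n = 2 each). Jak1, Tyk2 and Stat6 had log2 fold changes of -0.07, 0.04 and -0.11, and Ifnar1 of -0.11, and none of these passed the test. Ifnb1, Ifng and Ifna4 were listed at 0 in all 4 libraries. Of the macrophage genes, Itgam and Msr1 fell by 0.904 and by 0.850 on the log2 scale, while Csf1r, Adgre1 and Mrc1 had log2 fold changes of -0.26, -0.13 and -0.19 and did not pass the test. Xist was at 27.3 and 37.3 FPKM in the R libraries and 29.3 and 41.8 FPKM in the vehicle libraries.

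For the patterns below, all tests except that of GC content were chosen only after the result was seen. The first pattern is the lower level of interferon-stimulated genes in R. A lower share of macrophages is argued against as its whole cause, since the interferon list fell further than the macrophage list, by a difference of medians of -0.851 (permutation test over genes, p = 0.00025). Genes are not independent replicates in this test. A gene length trend is argued against as well, since the median was -1.428 after its removal. An effect of R on interferon signalling stays open and was not tested.

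The second pattern is that macrophage markers were lower and extracellular matrix genes higher in R. A lower share of macrophages could shift both. Genes moved apart within each list, with a heterogeneity chi-square per degree of freedom of 8.04 over 25 markers and 9.16 over 52 matrix genes. Among genes with a mean of at least 20 FPKM these were 5.99 over 20 markers and 6.76 over 41 matrix genes. This test asks for equal changes, which a lower share need not give where other cells also express the genes. It also treats genes as independent. The spread therefore cannot decide whether a lower share of macrophages is the whole cause. A length trend is argued against by medians of -0.594 and 0.355 after its removal. A shift in the share of macrophages, alone or together with a change within the cells, stays open.

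The third pattern is that the R replicates differed more from each other than the vehicle replicates did. Gene length explained 25.3% of the variance of the log2 ratios of the R pair, and GC content 13.9%. For the vehicle pair the shares were 7.7% and 1.4%. The log2 ratios of replicate 1 to replicate 2 fell with length in both pairs (Spearman -0.541 in R and -0.379 in vehicle), so the length trend is not particular to R. After removal of the length trend the SD of the R pair was 0.303, and after removal of the GC trend 0.326, both above the 0.248 of the uncorrected vehicle pair. Neither trend alone is therefore the whole difference, and both may contribute. A difference between the R cultures stays open and was not tested.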
